A study of Mus musculus with 17 samples.

How the data were processed

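The series holds 17 ChIP-seq libraries from KEC, a mouse kidney epithelial cell line. Of these, 8 were made with an HNF1b antibody, 4 with a TOP1 antibody and 5 from input chromatin. The HNF1b libraries form 4 groups of 2 replicates: asynchronous or mitotic wild-type cells, each fixed by aqueous crosslinking (AQC) or by non-aqueous crosslinking (NAQC). Groups were taken from the sample titles. The labels do not say whether replicates came from separate cultures. The TOP1 libraries, 2 of them from HNF1b-knockout cells, and the input libraries were not analysed here.

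The values came from 4 lists of HNF1b binding events, 1 per group. Per the labels, the authors called each list once on the 2 pooled replicates of its group, so no list gives a value per replicate and no spread between replicates can be had. The deposited lists are named for GEM and its GPS event caller; the caller's version, its control library and its threshold are not given in the sources used here. Bowtie2, SAMtools, deepTools and the build mm10 are named, without versions or roles, per the submitters' processing notes. Each event is a window of 201 bp centred on a point position. The deposited signal value of an event is the authors' own number, with no stated scaling for depth. The deposited −log10 q-value of an event is likewise the authors', with an upper limit of 999. Both were used only within their own list, to rank, split, filter or compare its events. Ranks and signals from lists of different length and depth are not comparable. The depth of the libraries is unknown. The lowest −log10 q was 2.03 in the asynchronous NAQC list, 2.04 in the mitotic NAQC list, 2.43 in the asynchronous AQC list and 3.38 in the mitotic AQC list.

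Gene positions came from a RefSeq table for assembly GRCm38.p6, whose chromosomes are those of mm10. It gave the outer ends and biotype of 21887 protein-coding genes and 2867 small RNA genes (snRNA, snoRNA, tRNA, rRNA and related types). It holds no strand, exons or sequence. In the design, 3 parts fixed before the data were examined therefore changed. The HNF1 motif tests were not run. The promoter tests were replaced by the share of events within 1000 bp of either outer end of a protein-coding gene, called a gene end below. A gene counted as holding an event when the event lay in its span or within 10 kb of either end, in place of 10 kb upstream only, and the 50 kb alternative was measured from the span. Whether an event lies in an exon, intron or UTR was not determined.

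Events of 2 lists were shared when their point positions lay within 100 bp. The share expected by chance came from 1000 random circular shifts of the partner list within chromosomes, each of at least 1 Mb. Shares carry 95% Wilson intervals, or exact Clopper-Pearson intervals for fewer than 100 events. These intervals cover counting error of events only. The signal of events with and without a partner was compared by the probability that an event with a partner has the higher value (0.5 with no difference), with a two-sided permutation test of 100000 resamples. Gene ends, gene spans and small RNA genes (events within 500 bp) were set against 100 circular shifts. Their relation to a partner was tested with a two-sided Fisher's exact test, and with a Mantel-Haenszel odds ratio within quartiles or deciles of the authors' signal, given with its 95% interval. For 10 gene lists with 194 genes in all, also written down beforehand, the number of members with an event was set against 10000 permutations of list membership among protein-coding genes within 20 bins of gene length (random lists below). The two-sided permutation p-values were Benjamini-Hochberg adjusted over the 10 lists, with a threshold of 0.05. All 194 symbols matched the gene table. P-values compare events or genes within pooled lists and say nothing about the spread between cultures.

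By a rule fixed at the same time, named are the listed genes with a mitotic NAQC event (the 25 of 29 with the highest asynchronous NAQC signal), the nearest protein-coding genes of the 10 highest events in each NAQC list, those of the 10 highest events in either NAQC list that lack a partner in the other, those of the 5 highest asynchronous AQC events and the 10 highest mitotic AQC events, and Hnf1b.

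The procedures were tested on simulated data. With 200, 1000 or 2600 of 2740 simulated events placed at asynchronous NAQC positions, 208, 1002 and 2600 were found shared. With true odds ratios of 1, 0.5 and 0.2 within deciles over 17044 events, the median Mantel-Haenszel estimates were 1.003, 0.501 and 0.202 over 100 simulations each. Simulated events were independent, and their chance of a partner did not vary with signal inside a decile. Clustering of events and signal differences within deciles were thus not tested. For mitotic NAQC events over 21887 genes, 4 of 200 random gene lists and 200 of 200 lists with 10 of 22 members holding an event were called at an unadjusted p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

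Alternatives fixed in advance were sharing distances of 50, 200 and 500 bp, only events above the median −log10 q of each list, the longer list reduced to the length of the shorter, merging of events within 500 bp, −log10 q in place of the signal, and other assignments of events to genes. Added after seeing the data were the gene-end measures with their windows and strata, the tests at small RNA genes, the removal of events at small RNA genes, the restriction to the highest event per Mb at gene ends or small RNA genes, and matching of random genes on territory in place of gene length, where territory is the length of genome for which a gene is the nearest protein-coding gene, counted on a 5 kb grid.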

Results

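HNF1b, a homeodomain transcription factor of the kidney tubule, was mapped by ChIP-seq in KEC mouse kidney epithelial cells. The series title calls HNF1b a bookmarking factor, a term for factors that stay on chromosomes through mitosis. Asynchronous cells were compared with cells arrested in mitosis by thymidine (2 mM, 24 h) and then STLC, an inhibitor of a spindle kinesin (5 µM, 8 to 14 h). Cells were fixed either in a water-based solution (AQC) or without water (NAQC). Each of the 4 groups had 2 HNF1b libraries, which the authors pooled before calling events. There is thus 1 list per group, no replicate error and no known depth. Intervals below describe counting of events only. Coordinates are mm10, and every signal value is the authors' own, readable only within its list.

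In asynchronous cells fixed by NAQC, 17046 HNF1b events were listed. The highest lay in Zmynd8, which encodes a chromatin reader (chromosome 2, 165857466 to 165857666, signal 20112). The next were in Eya2, a transcriptional coactivator gene (chromosome 2, 165667232 to 165667432, 14622), and in Tchp, which encodes a keratin-binding protein (chromosome 5, 114719174 to 114719374, 12394). Further leading events lay in Met, the receptor gene for hepatocyte growth factor (8273), and in D630003M21Rik (8593). Others lay 3.73 kb from the cell polarity gene Pard6b (8765), 98 bp from the aldo-keto reductase gene Akr1c13 (9818), 24.3 kb from Glrp1 (9171) and 51.5 kb from Hmgb1 (9952). One leading event on chromosome X (15753736 to 15753936, 8276) was 769 kb from its nearest protein-coding gene, Cypt1.

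The mitotic NAQC list held 2740 events, and almost all of them were asynchronous sites. Of these 2740, 2695 had an asynchronous NAQC event within 100 bp (98.4%, Wilson 95% interval 97.8 to 98.8), at a median distance of 7 bp. Seen from the asynchronous side, 2750 of 17046 events had a mitotic event (16.1%, 15.6 to 16.7). Chance gave 0.138% and 0.0230%, and 0 of 1000 random shifts reached either share. The highest mitotic event was the one on chromosome X (15753734 to 15753934, signal 3352), followed by Zmynd8 (3144). Nsmce2, a SUMO ligase gene of the SMC5/6 complex, held the third (chromosome 15, 59480614 to 59480814, 2400). The others in the top 10 were near Hmgb1 and Akr1c13 and in Tchp, Eya2, Notch1, the corepressor gene Tle4 and the kinase gene Sgk2. Each of these 10 lay within 18 bp of an asynchronous event. The asynchronous list is longer than the mitotic one. Reduced to its 2740 highest events, 69.1% of them had a mitotic event and 68.0% of the mitotic events had one of them as partner.

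Whether an asynchronous site also had a mitotic event went with its asynchronous signal. All of the 100 highest asynchronous events, 496 of the 500 highest and 944 of the 1000 highest had one. By deciles of the list, the share was 83.6% in the highest (81.7 to 85.3), 38.9% in the next (36.6 to 41.2), 5.05% in the fifth (4.10 to 6.19) and 0.469% in the lowest (0.238 to 0.924). Events with a mitotic partner had a median signal of 1197, against 297 without. The probability that the former had the higher signal was 0.919 (two-sided permutation p = 1e-05, the smallest that the resamples can give). The test compares events of a pooled list, not cultures.

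**Figure D1:**
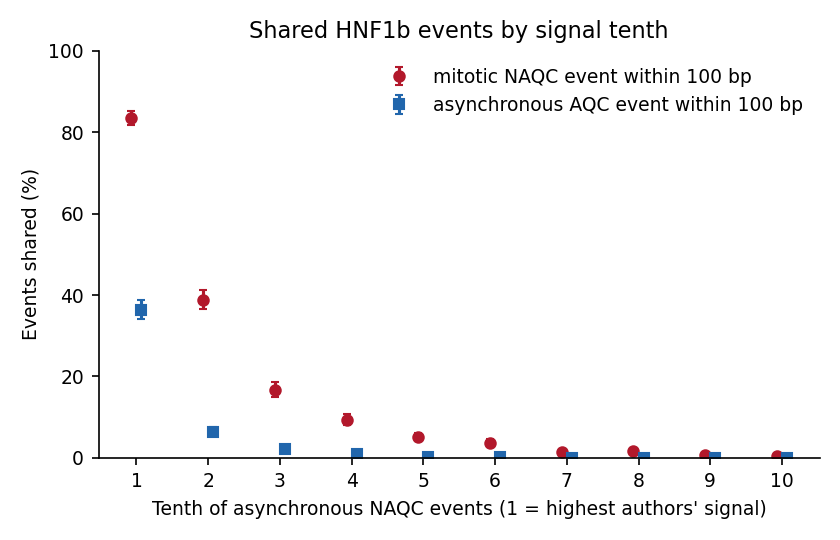
Share of asynchronous NAQC events (y axis, percent) with a mitotic NAQC event (circles) or an asynchronous AQC event (squares) within 100 bp, by decile of the authors' signal (x axis, 1 is the highest). Bars are Wilson 95% intervals; the shares fall from 83.6% and 36.4% in the highest decile to 0.469% and 0% in the lowest.

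The strongest asynchronous sites without a mitotic event began at rank 410, 21.7 kb from Slc4a1ap (chromosome 5, 31583332 to 31583532, signal 2804). The others among the 10 highest lay 835 bp from the tyrosine kinase gene Src (2605), 95 bp from Sirt4 inside the snRNA gene Gm24407 (2603), in Kif21a (2570) and 686 bp from Cacul1 (2499). The remainder were in Scarb1, the HDL receptor gene (2428), 8.44 kb from the chemokine gene Ccl5 (2422), in the microRNA exporter gene Xpo5 (2348), 11.5 kb from Neurl1b (2347) and in Plekha2 (2292). In the other direction, 45 mitotic events had no asynchronous partner, and their median mitotic signal was 111, against 183 for the rest. The probability that such an event had the higher signal was 0.281 (two-sided permutation p = 1e-05). The highest lay 1.55 kb from the importin gene Kpna1 (chromosome 16, 35981641 to 35981841, 731). Next were events 89.3 kb from 9530057J20Rik (689), 10.2 kb from Gm15319 (608) and in 4930467E23Rik (567). Events 9.65 kb from Gm9495 (361) and 24.0 kb from Glrp1 (328) followed. The Kpna1 event had its nearest asynchronous event 112367 bp away, whereas each event from 9530057J20Rik to Glrp1 had one 155 to 352 bp away. The other 4 lay 136 kb from Cpe (244), in Cbwd1 (212), 7.72 kb from Pllp (206) and in Bcas1 (182), their nearest protein-coding genes. The event at Pllp was 45 bp from the tRNA gene n-TLcag4. Of the 45, 11 had an asynchronous event within 500 bp and 27 had none within 10 kb.

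Hnf1b itself held 7 asynchronous NAQC events in its span (chromosome 11, 83850209 to 83905917) or within 10 kb. The highest, at 83852011 to 83852211, had a signal of 1268 and rank 1504. The single mitotic NAQC event lay at the same site (83852001 to 83852201, signal 336, rank 587 of 2740). Neither AQC list had an event there.

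**Figure D2:**
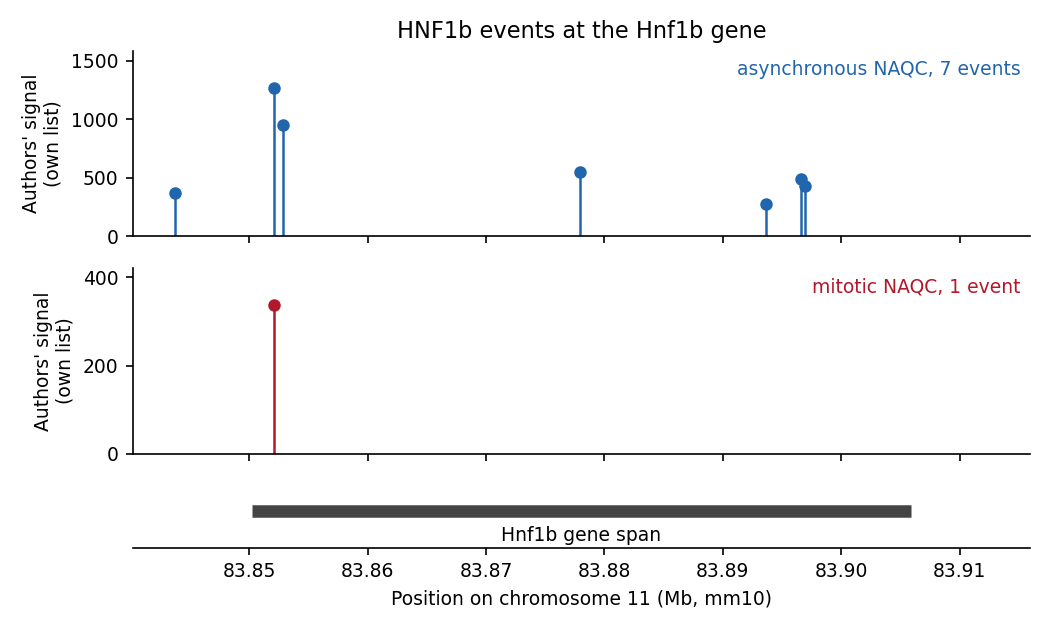
HNF1b events along the Hnf1b gene and 10 kb to either side (x axis, Mb on chromosome 11, mm10), with the authors' signal on the y axis of each list's own panel and the gene span below. The asynchronous NAQC list has 7 events and the mitotic NAQC list 1, at the position of the highest asynchronous event.

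Earlier known HNF1B target genes held mitotic sites more often than random genes of their length. Of 22 such genes, 8 held a mitotic NAQC event, against a median of 2 in random lists (95% of lists 0 to 5, Benjamini-Hochberg adjusted permutation p = 0.012). They were Pkhd1, the gene of recessive polycystic kidney disease (chromosome 1, 20057779 to 20618082, 3 events), Bicc1 (4), Glis3 (4), Glis2 (2), Pcbd1, which encodes the dimerization cofactor of HNF1 (1), the potassium channel gene Kcnj16 (1), the cystin gene Cys1 (1) and the polarity gene Crb3 (1). With events up to 50 kb from a gene counted, 10 members had an event and the call was lost (adjusted permutation p = 0.094). By nearest gene it stood, with 10 members against a median of 2, or of 3 with matching on territory (adjusted permutation p = 0.002 for each). In the asynchronous list, 12 of the 22 genes held an event, against a median of 8 (adjusted permutation p = 0.623), and the difference between the NAQC lists was not tested. Against genes with equally strong asynchronous sites, the 8 mitotic genes among these 12 equalled the random median of 8 (adjusted permutation p = 1).

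No other list passed the adjusted threshold with this assignment of events to genes, in either NAQC list. For the asynchronous list, the adjusted permutation p of the 10 lists ranged from 0.623 to 0.753. Of 23 cystic kidney and cilium genes, 13 held an asynchronous event (median 11) and 8 a mitotic event (median 3, adjusted permutation p = 0.093). The mitotic 8 included Nek8, Ift140 and Dcdc2a, and 5 of them are also in the list of earlier targets. Of 25 tubular transporter genes, 13 held an asynchronous event (median 10) and 6 a mitotic event (median 3, adjusted permutation p = 0.215). Among the 6 were the endocytic receptor genes Lrp2 and Cubn, the amino acid transporter gene Slc6a19 and the bicarbonate transporter gene Slc4a4. Of 24 epithelial junction genes, 13 held an asynchronous event (median 9). A mitotic event was held by 6, namely Pard6b, Pard3, Cdh16, Cdh6, Tjp2 and Crb3 (median 2, adjusted permutation p = 0.155).

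Of 29 kidney transcription factor and Notch genes, 12 held an asynchronous event (median 10). A mitotic event was held by 5, namely Pax2, Pax8, Hnf1b, Notch2 and Lef1 (median 2, adjusted permutation p = 0.458). By asynchronous signal, the highest listed genes were Pard6b (8765), Pax2 (7220), Cdh16 (6573) and Glis3 (5514), whose mitotic signals were 1239, 1617, 674 and 877. When an event was instead given to its nearest protein-coding gene, this list passed the threshold, with 22 members in the asynchronous list (median 10, adjusted permutation p = 0.002) and 12 in the mitotic list (median 3, adjusted permutation p = 0.002). The asynchronous call was lost when random genes were matched on territory in place of length (median 16, adjusted permutation p = 0.105), and the mitotic call held (median 6, adjusted permutation p = 0.044).

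Lists of other programmes were not told from random genes in either NAQC list. Among 18 mesenchymal genes, 9 held an asynchronous event (median 7) and 2 a mitotic event, Cdh2 and Twist2 (median 2, adjusted permutation p = 1). Of 24 liver and gut HNF1 targets, 6 held an asynchronous event (median 8) and 1, Afp, a mitotic event (median 2, adjusted permutation p = 0.997). Lef1, Twist2 and Afp were named after their values were seen. Mitosis and cell cycle genes held asynchronous events in 6 of 21 cases (median 7), reference housekeeping genes in 6 of 14 (median 4) and markers of other kidney cell types in 4 of 14 (median 6). A mitotic event was held by 0 members of each of these 3 lists, against medians of 2, 1 and 2 (adjusted permutation p = 0.469, 0.997 and 0.469), and since 0 is the lowest count possible, a lower frequency than in random genes could not have been detected.

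**Figure D3:**
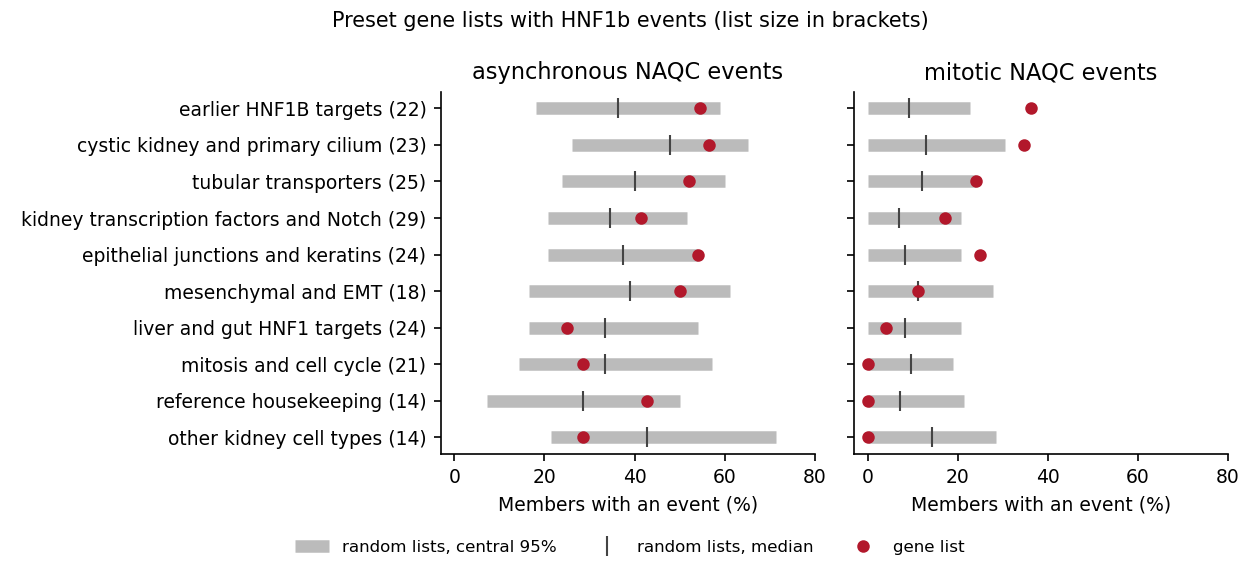
Share of each gene list's members (x axis, percent) with an asynchronous NAQC event (left) or a mitotic NAQC event (right) in the gene span or within 10 kb. Red points are the lists (sizes in brackets), grey bars the central 95% and ticks the median of 10000 random lists matched on gene length; 8 of 22 earlier HNF1B targets hold a mitotic event, against a random range of 0 to 5.

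HNF1b events favoured genes and gene ends in both NAQC lists. Gene spans held 49.6% of asynchronous and 50.2% of mitotic events, against 39.9% and 40.2% after random shifts, of which the highest gave 42.0% and 42.4%. Gene ends held 9.12% of asynchronous events (8.69 to 9.56) and 8.43% of mitotic events (7.45 to 9.53), against 3.06% and 3.0% after shifts. Without regard to strength, asynchronous events at gene ends were not shown to differ from the rest in having a mitotic partner (odds ratio 0.889, 95% interval 0.769 to 1.03, Fisher's exact p = 0.12). Within deciles of the signal they had one less often (Mantel-Haenszel odds ratio 0.550, 95% interval 0.452 to 0.670). With the window narrowed to 500 bp, the unadjusted odds ratio was 0.750 (Fisher's exact p = 0.00105). With the window widened to 2.5 kb, the unadjusted odds ratio changed direction (1.06, Fisher's exact p = 0.323), and that within deciles was 0.744 (0.638 to 0.867). With only the highest gene-end event per Mb, set against all other events, the odds ratio without regard to strength was reversed (1.52, Fisher's exact p = 4.08e-06). The kept events are the stronger ones by construction, so this reversal is no evidence about gene ends. Within deciles the odds ratio was 0.746 (0.585 to 0.951).

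In asynchronous cells, the AQC list held 788 events, and 748 of them had a NAQC event within 100 bp (94.9%, 93.2 to 96.3). Of the asynchronous NAQC events, 786 of 17046 had an AQC event (4.61%, 4.31 to 4.94). Chance gave 0.134% and 0.00642%, and 0 of 1000 shifts reached either share. Of the 100 highest NAQC events, 89 had an AQC event. The NAQC events with an AQC partner had a median signal of 2292, against 327 without, and the probability that the former had the higher signal was 0.954 (two-sided permutation p = 1e-05, again the smallest possible). With the NAQC list reduced to its 788 highest events, 56.7% of them had an AQC event and 55.2% of the AQC events had one of them as partner. Of the 788 AQC events, 632 had a mitotic NAQC event (80.2%, 77.3 to 82.8).

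At the head of the asynchronous AQC list were small RNA genes. Of its 25 highest events, 21 lay within 500 bp of a small RNA gene (84.0%, exact interval 63.9 to 95.5). In the whole list it was 74 of 788 (9.39%, 7.55 to 11.6), of which 71 were at genes annotated as snRNA. The highest event overlapped the snRNA gene Gm24265 in Sirt4 (chromosome 5, 115489476 to 115489676, signal 1561). The third and the fifth overlapped genes annotated as snRNA in Tex14, where the gene is the U3 RNA gene Rnu3b1 (1342), and in Rdm1 (1302). Many such genes have near-identical copies, and how reads shared between copies were assigned is not given in the sources used here. The second lay in Eya2 (1432). The fourth, whose nearest protein-coding gene is Scyl1, lay 490 bp from Malat1, an abundant nuclear RNA (1324). In the NAQC lists, small RNA genes held 154 of 17046 asynchronous events (0.903%) and 18 of 2740 mitotic events (0.657%), with 0 among the 100 highest of either (Wilson upper bound 3.70%). Random shifts gave 0.115%, 0.116% and 0.117% in the asynchronous NAQC, mitotic NAQC and asynchronous AQC lists.

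These sites were mostly absent from the mitotic NAQC list. For AQC events, this comparison changes fixation as well as cell-cycle stage. Of the 74 AQC events at small RNA genes, 63 had an asynchronous NAQC event and 3 a mitotic NAQC event, whereas 629 of the other 714 had a mitotic NAQC event (odds ratio 0.00571, Fisher's exact p = 6.79e-53). The 74 events lay at 46 genes and are not independent; with only the highest event of each kind per Mb, 2 of 21 and 511 of 575 had a mitotic NAQC event (odds ratio 0.0132, Fisher's exact p = 1.3e-15). Among asynchronous NAQC events, those at small RNA genes had a mitotic partner less often than others within deciles of the signal (Mantel-Haenszel odds ratio 0.166, 95% interval 0.0958 to 0.287). With only the highest of them per Mb, set against all other events, it was 0.461 (0.228 to 0.930). Without regard to strength the odds ratio was 0.600 (Fisher's exact p = 0.0604), or 1.60 with the highest per Mb (Fisher's exact p = 0.142). The kept events are the stronger ones by construction.

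**Figure D4:**
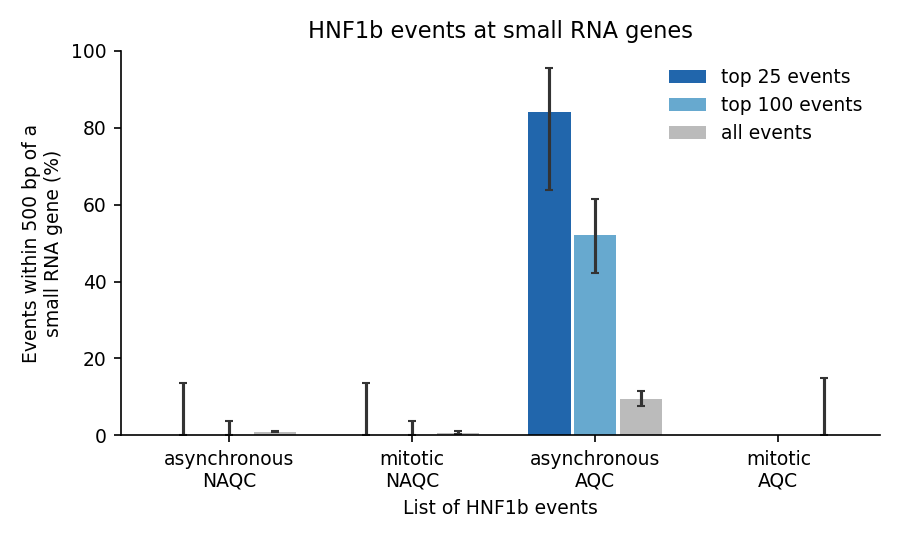
Share of HNF1b events within 500 bp of a small RNA gene (y axis, percent) in each list (x axis), for the 25 highest, the 100 highest and all events; the mitotic AQC list has 23 events and only its whole is drawn. Bars carry 95% intervals (exact below 100 events, otherwise Wilson), and the asynchronous AQC list reaches 84.0% in its 25 highest events and 9.39% overall.

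In mitotic cells AQC gave 23 events. Of these, 15 had a mitotic NAQC event (65.2%, exact interval 42.7 to 83.6), 16 an asynchronous NAQC event (69.6%, 47.1 to 86.8) and 14 an asynchronous AQC event (60.9%, 38.5 to 80.3). Chance gave 0.0217%, 0.143% and 0.0217%, and 0 of 1000 shifts reached any of the 3 shares. None of the 23 lay at a small RNA gene (exact upper bound 14.8%). The site on chromosome X near Cypt1 again led (signal 346), and Zmynd8 (241), the TGF-beta inhibitor gene Smad7 (237), Tle4 (197) and Tchp (184) were among the 10 highest. So were sites 115 bp from Akr1c13 (212) and 133 bp from its neighbour Akr1c12 (188), 373 kb from the activin receptor gene Acvr2a (210) and 26.6 kb from Zfp36l2 (167). The second highest, 195 kb from Cr2 (chromosome 1, 195371741 to 195371941, 302), had an asynchronous NAQC event 8 bp away and no mitotic NAQC event within 748018 bp. Its −log10 q was 3.56, close to the lowest of the list (3.38). The other 9, with −log10 q from 17.4 to 57.7, each had a mitotic NAQC event within 23 bp.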

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

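No paired analysis was possible because each list pools the replicates of its group, and for the same reason no replicate could be left out. The gene-end and small RNA results, the removal of events at small RNA genes, the limit of 1 event per Mb and the matching on territory were chosen after seeing the data. The motif and promoter alternatives were not run, since neither sequence nor strand was used here. Of the alternatives fixed beforehand, 55 kept the result, 9 moved a share beyond its interval, 3 gained a call and 1 lost one. Of the added ones, 26 kept it, 5 moved a share, 9 gained a call and 3 reversed an odds ratio. List length mattered most. With the longer list reduced to the length of the shorter, the share of asynchronous NAQC events with a mitotic event was 69.1%, the reverse share 68.0%, the share with an AQC event 56.7% and its reverse 55.2%. By construction the reduced list holds only its strongest events, which raised the shares of asynchronous NAQC events. It also offers fewer partners, which lowered the reverse shares. With events shared within 500 bp, the shares of asynchronous NAQC events were 17.5% (mitotic) and 5.30% (AQC). Within 50 bp, 91.1% of AQC events had a NAQC event. Among events above the median −log10 q of each list, the mitotic share was 98.8% and the AQC share 97.2%. Without small RNA genes, 4.22% of asynchronous NAQC events had an AQC event. The probability behind the strength result ranged from 0.897 to 0.930, and the mitotic AQC share was 65.2% within 50, 200 and 500 bp and without small RNA genes, the alternatives run for it. Gene ends held 6.96% and 15.1% of asynchronous and 5.47% and 15.8% of mitotic events with windows of 500 bp and 2.5 kb, as the windows' size requires. The gene-end odds ratio of 0.889 was 0.551 within quartiles, 0.550 within deciles, 0.750 at 500 bp and 1.06 at 2.5 kb. For small RNA genes it was 0.153 within quartiles and 0.166 within deciles. With only the highest event per Mb at these places, the gene-end odds ratio was 1.52, or 0.746 within deciles, and the small RNA odds ratio 1.60, or 0.461 within deciles; the kept events are by construction the stronger ones. Among gene lists, earlier HNF1B targets lost the mitotic call at 50 kb (10 members) and kept it by nearest gene with either matching (10 members, adjusted p of 0.002). By nearest gene, kidney transcription factors and Notch gained calls (22 asynchronous, 12 mitotic members), as did epithelial junctions (15 asynchronous). Both asynchronous calls were lost with matching on territory (adjusted p of 0.105 and 0.076). In the mitotic list, that matching gave calls for the 12 and for 7 junction members, each at an adjusted p of 0.044. For the changed gene-end and gene-list calls the cause was not tested. The unknown depth limits every statement on sites without a mitotic or AQC event, which may be bound below the callers' threshold: 0.469% of the lowest but 83.6% of the highest decile had a mitotic event.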

Other observations

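All tests in this part were chosen after seeing the lists, and for those at gene ends and at ribosomal protein and histone genes the outcome that would count against the explanation was written before the result was seen. No gene list was told from other genes with equally strong asynchronous sites in how many members held a mitotic event. Among the 12 earlier HNF1B targets with an asynchronous event, 8 had a mitotic event, against a median of 8 in random genes matched on their strongest asynchronous signal (95% of lists 6 to 9, adjusted permutation p = 1). For the 13 cystic kidney and cilium genes it was 8 against 8, and for the 13 epithelial junction genes 6 against 5 (adjusted permutation p = 1 for each). The 6 mitosis and cell cycle genes with an asynchronous event, among them Cenpe (3 events), Tpx2 (4) and Top1 (1), named after their values were seen, had a mitotic event in 0 cases, against a random median of 1 (0 to 3, adjusted permutation p = 1). Of the 22 earlier targets, 5 (Pkhd1, Bicc1, Pcbd1, Glis3 and Cys1) also held an asynchronous AQC event, against a median of 0 (0 to 3, adjusted permutation p = 0.01). This call was lost with events up to 50 kb from a gene (adjusted permutation p = 0.184) and stood by nearest gene (6 members, 0.001, and 0.006 with matching on territory). No other list passed in the AQC list by span or within 50 kb. Kidney transcription factors and Notch, with 2 of 29 by span (adjusted permutation p = 0.712) and 4 within 50 kb (0.443), passed only by nearest gene (7 members, 0.001, and 0.031 with matching on territory). Cystic kidney and cilium genes (0.109 by span, 0.443 within 50 kb, 0.105 by nearest gene) and epithelial junction genes (0.201, 0.443 and 0.0793) passed only by nearest gene with matching on territory (adjusted permutation p = 0.0475 and 0.0367).

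The genes with most mitotic NAQC events were long ones: Ano6, Arhgef28, Ext1, Lpp and Rad51b, each with 5. Asynchronous NAQC events were sparser on chromosome X (1.98 per Mb) than on any autosome (5.02 to 11.6 per Mb). Copy number and mappable length of the chromosomes were not taken into account. On chromosome 8 between 19 and 22 Mb, 14 mitotic and 23 asynchronous events were listed. This stretch also held 3 of the 45 mitotic events without an asynchronous partner, and each of the 3 had an asynchronous event within 500 bp. Asynchronous NAQC events with an AQC partner away from small RNA genes had a mitotic event in 92.1% of 713 cases. The odds ratio against all others was 79.8 without regard to strength, 18 within quartiles and 8.36 within deciles of the signal (95% interval 6.0 to 11.6). With small RNA genes kept in, 84.1% of 786 events with an AQC partner had a mitotic event. Their odds ratio within deciles was 3.23 (2.55 to 4.10). Since the odds ratio fell with finer strata, differences in signal within deciles may still enter.

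Mitotic events were mainly the strongest asynchronous events, and a candidate explanation is that the mitotic list is only less sensitive, so that sites of equal strength are lost alike. The tables argue against loss by decile of signal alone, since the odds ratios of a mitotic event within deciles of the signal were below 1. They were 0.550 (0.452 to 0.670) at gene ends and 0.166 (0.0958 to 0.287) at small RNA genes. With only the highest event per Mb at such places, they were 0.746 (0.585 to 0.951) and 0.461 (0.228 to 0.930), closer to 1 and still below it. With events at small RNA genes left out, the gene-end odds ratio within deciles was 0.570 (0.466 to 0.697). Of the 154 asynchronous NAQC events at small RNA genes, 73 had an AQC partner. Their odds ratio thus partly repeats the loss already seen among AQC events. The highest decile spans signals from 1147 to 20112, so differences in signal within deciles may enter here too. Within quartiles the odds ratios were 0.551 at gene ends and 0.153 at small RNA genes, close to those within deciles. Strata of −log10 q were not used, and events of equal signal need not be equally easy to call. Lower sensitivity that differs between places is therefore not excluded. Lower sensitivity, a smaller bound fraction in mitosis and a difference in depth all stay open, because the lists carry neither depth nor replicates. The cell-cycle difference named by the design remains untested. Thymidine and STLC were listed only for the mitotic libraries, so drug exposure cannot be told apart from cell-cycle stage. The share of the arrested cells that were in mitosis was not examined here.

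Small RNA genes led the asynchronous AQC list. Reads shared between near-identical copies may raise such genes, and this stays open: of 8 abundant noncoding RNA genes taken as single loci, 1 (Rnu12, named after its value was seen) had an AQC event within 500 bp, against a random median of 0 (95% of lists up to 1, two-sided permutation p = 0.0628). Another 3 such genes, Malat1, Rnu11 and Snord118, were left out of this test because their AQC events had been seen before the genes were listed. Signal at abundantly transcribed genes in general cannot be told apart from chance here: 0 of 142 ribosomal protein and histone genes had an AQC event, but random lists also held a median of 0, so the bound written beforehand could not separate the outcomes. Fixation chemistry, the difference named by the design, stays open as an untested explanation.

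Of the mitotic AQC events, 8 of 23 had no mitotic NAQC partner, and 6 of these 8 had no asynchronous NAQC event either. Calls near the authors' threshold may account for them: their mean −log10 q was 5.56, against 25.4 for the 15 with a partner, a difference of -19.9 (two-sided exact permutation p = 3.67e-05). Displaced positions of shared sites are argued against, since 0 of the 8 had a mitotic NAQC event within 500 bp. Whether any of the 8 is bound in mitotic cells stays open.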
